A study of Mus musculus with 8 samples.

How the data were processed

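RNA sequencing libraries were made from 8 cultures of mouse CD8 T cells, 4 treated with the DOT1L inhibitor SGC-0946 and 4 with the vehicle DMSO. Per the labels' protocols, 2 ug of yeast total RNA was added to each sample as a reference and libraries were prepared with a stranded mRNA kit. The deposited table holds raw read counts, as whole numbers, for 21625 mouse genes in 8 sample columns, together with gene symbols, biotypes and coordinates. Per the submitters' processing notes, the genome build was mm10 and the tools named were TopHat2 2.1, Bowtie 1.1, TopHat and HTSeq, with no role or order given. The annotation release, the strand setting used in counting and any filter are not given in the sources used here. No yeast genes were analysed here, so the planned share of yeast counts and the planned scaling to yeast RNA were not computed, and total RNA per cell could not be compared between the arms. Changes are therefore relative to the other mouse genes.

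Of the 21625 gene identifiers, 21589 were found in the GENCODE mouse release M21 annotation, 21394 of them with the same start and end and 21039 with the same symbol. Symbols and coordinates in the text are those of the deposited table. Without a known strand setting, reads of overlapping or antisense genes cannot be separated with certainty. Genes with close relatives, such as granzymes, killer cell lectin-like receptors, serpins of the Serpinb9 group, H2 class I genes and T cell receptor constant regions, are uncertain where reads were shared.

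Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by the edgeR expression filter with a minimum count of 10 and a minimum total of 15, which left 10900 genes holding at least 99.6% of the counts of each library. Libraries were scaled by TMM (trimmed mean of M values), and the quasi-likelihood test compared SGC-0946 with DMSO, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM are counts scaled by the TMM-adjusted library size, and means are given with the SD over 4 libraries. The same test with a sex by treatment term compared the effect in 2 male and 2 female pairs. The 38 gene lists were tested with camera in limma 3.58.1 on voom-weighted log2 CPM, with a preset correlation of 0.01, where at least 3 members were tested. Library totals and shares were compared with exact permutation tests over 70 assignments, two-sided, and, chosen after seeing the data, over the 16 assignments that exchange labels within pairs. Groups, tests, gene lists and the alternatives named as planned were fixed before the data were examined.

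The named genes follow a rule. It takes the 10 largest rises and the 10 largest falls among genes past the threshold with an average log2 CPM of at least 1 and the same direction in all 4 equally numbered pairs, leaving out predicted genes. It adds the 3 members of each list with the smallest p, Dot1l itself, and the 5 genes with the smallest p for the difference between sexes if any passes, otherwise the 1 gene with the smallest p. Prf1, Gzma, Gzmb, Cd8a, Ifng, Kit, Tcf7, Cd5, Serpinb9b, Fcgr3, Tyrobp, Me1, Ctsg, Cma1 and Mcpt8, Gzmn, Mir6236, the sex-linked genes, the members named only as moving against their list, and all genes given without a value of their own were chosen after their values were seen. A fold against an arm without counts was computed against a floor of 3 counts over the arm. With 1 to 3 counts, the ratio of summed counts is given with its exact 95% interval, which covers counting error only.

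The replicate numbers pair the samples. Library names carry the same mouse number in both arms, and deviations from the arm means correlated at 0.34, 0.33, 0.38 and 0.31 between equally numbered samples, each sample correlating best with its own number. Correlations with the other number of the same sex were 0.06 to 0.22, and those with the other sex were negative. All replicate pairs within an arm differed by more than sampling noise, with chi-square per degree of freedom from 1.71 to 7.77, so each library was counted once. The labels call the samples biological replicates. The main tests held no term for these pairs, and a replicate block was run as an alternative.

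Alternatives were other scalings (RLE size factors, library size only), other count filters, DESeq2 1.42.0, limma-voom, a replicate block, sex as a covariate and leaving out libraries or pairs. Gene lists were also tested with an estimated correlation and with fry. Thinning all libraries to the smallest total, a filter of 5 CPM in 4 samples and the counts of genes ranked by level were chosen after seeing the data. On simulated counts for 10900 genes, the comparison of the arms recovered 67% of genes changed 1.5-fold and 97% of genes changed 3-fold, with 8 false calls. The sex by treatment test recovered 11% and 77%, with 12 false calls. In simulated lists the list test called the moved list and 0 of the unmoved ones, with genes drawn independently, which leaves correlated genes untested.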

Results

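Transcript levels were measured in mouse CD8 T cells after 8 days of culture with an inhibitor of DOT1L, a histone methyltransferase. The cells came from animals carrying OT-I, a transgenic T cell receptor, and with unmodified alleles at the other engineered loci of the strain. They were activated through CD3 and CD28, and SGC-0946 or 0.1% DMSO was given every 2 days. The dose of the inhibitor is recorded as 10 mM in the treatment text and 10 uM in the library names, and the labels do not settle which holds. Each arm had 4 biological replicates, 2 male (replicates 1 and 2) and 2 female (replicates 3 and 4). Xist and the Y-linked gene Ddx3y matched the recorded sex in all 8 libraries. The study asked how loss of DOT1L activity alters the transcriptome of these cells.

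The DMSO libraries held 3566569, 3514221, 4034253 and 4711211 counts (replicates 1 to 4) and the SGC-0946 libraries 5484329, 5366789, 6691808 and 4858636. The total was higher with SGC-0946 in all 4 pairs (3.96 ± 0.555 M against 5.60 ± 0.777 M, SD, n = 4 each). The exact permutation p was 0.0286 over 70 assignments, and 0.125 with labels exchanged only within the 4 pairs, in each case the smallest the design allows. The totals count mouse genes only, so sequencing depth and the share of added yeast RNA cannot be told apart in them. The first principal component, with 66.7% of the variance, separated the treatments, and the second, with 11.7%, separated male from female libraries. SGC replicate 4 differed most from its arm, with chi-square per degree of freedom of 5.85 to 7.77 against the other SGC-0946 libraries.

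**Figure D1:**
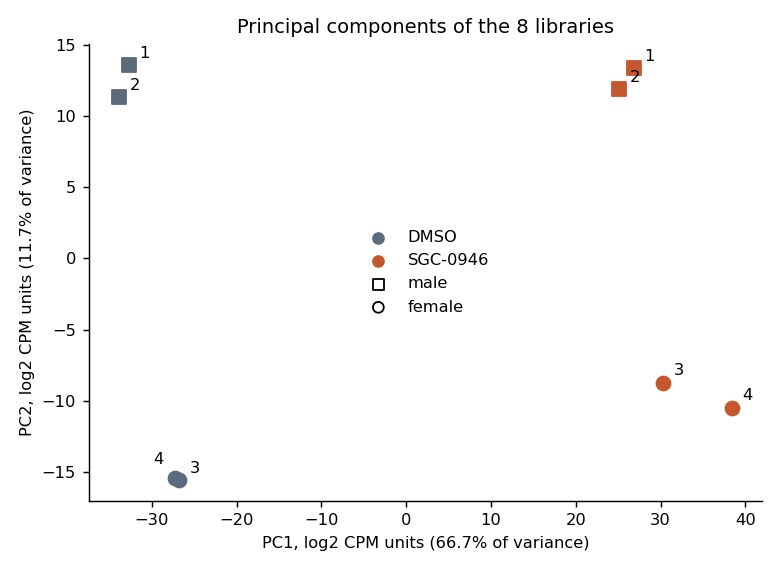
Principal components of log2 CPM for the 8 libraries, with the first component on the x axis (66.7% of variance) and the second on the y axis (11.7%). Colours mark the treatment, shapes the sex and numbers the replicate, and the 4 DMSO libraries lie apart from the 4 SGC-0946 libraries along the first component.

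The first comparison asked what inhibition of DOT1L changed. Of 23 tested cytotoxic granule and death ligand genes, 18 rose with SGC-0946 and 5, Gzmb among them, did not pass. Gzmc, a granzyme, went from 5.71 ± 2.35 to 197 ± 65.8 CPM (SD, n = 4 each), and Prf1, the pore-forming perforin, from 20.9 ± 1.91 to 186 ± 90.8 CPM. The receptor genes Klrb1c (NK1.1), Cd244a and Fcer1g, familiar from NK cells, rose 16.9-fold, 12.7-fold and 7.15-fold. The coreceptor genes Cd8a and Cd8b1 fell 3.10-fold and 2.53-fold, and Trac, the constant region of the T cell receptor alpha chain, fell 2.60-fold. Satb1, Ccr7 and Cd27, genes of resting and central memory T cells, fell too. In all, 4041 of 10900 tested genes changed in edgeR's quasi-likelihood test without a term for the pairs, 2014 higher and 2027 lower. With the replicate block the test called 4736 genes, 2393 higher and 2343 lower. In the fit without the block, changes of at least 2-fold were more often rises, with 507 genes against 191. Ranked by the mean log2 CPM of both arms, the lowest 2180 genes held 367 rises and 86 falls of that size and the highest 2180 held 13 and 25. Of the highest 8720 genes by DMSO level alone 85 rose and 131 fell, and by SGC-0946 level alone 225 rose and 73 fell. Without SGC replicate 4 the test called 4081 genes. Of these, the genes higher by at least 2-fold with SGC-0946 numbered 530 and the genes lower by at least 2-fold with SGC-0946 numbered 178.

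**Figure D2:**
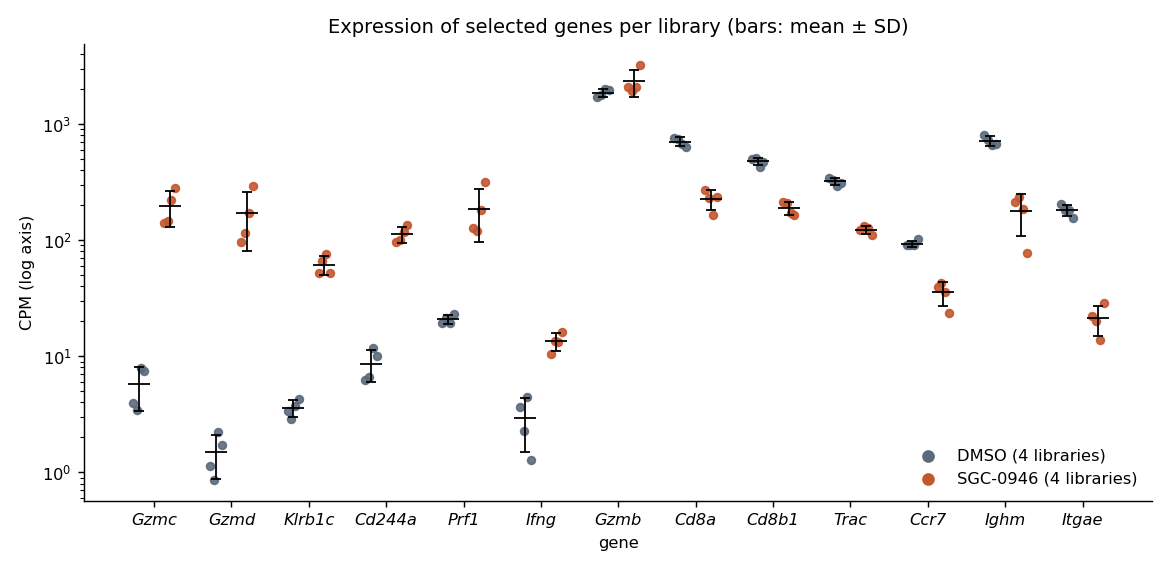
CPM per library on a log axis for 13 genes in DMSO and SGC-0946 cultures (4 libraries each), with points for libraries and bars for mean ± SD. Gzmc, Gzmd, Klrb1c, Cd244a, Prf1 and Ifng lie higher in all 4 SGC-0946 libraries than in any DMSO library, Gzmb overlaps, and Cd8a, Cd8b1, Trac, Ccr7, Ighm and Itgae lie lower.

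The largest rises by the naming rule were in Gzmg, Gfra1, Gzme, Gzmd, Tns3, Dixdc1, Emp2, Adamts14, Alox5 and Scin. Gzmd (chromosome 14, 56129556 to 56132608, mm10) had 1.49 ± 0.617 CPM in DMSO and 169.9 ± 89.6 CPM with SGC-0946 (log2 fold change 6.77, SE 0.48, edgeR adjusted p = 1.03e-07). Gzme had 0.578 ± 0.612 and 84.6 ± 44.3 CPM (log2 fold change 6.99, SE 0.54, edgeR adjusted p = 2.48e-07). Its DMSO mean rests largely on DMSO replicate 4, at 1.5 CPM against 0.249 to 0.286 CPM in the other DMSO libraries. Gfra1, a co-receptor for GDNF, had 0 counts in DMSO and 83 with SGC-0946, 19.4-fold higher against the floor of 3 counts (lower limit of the exact 95% interval of the ratio 15.4). Gzmg had 1 count in DMSO and 510 with SGC-0946, a ratio of 358 (exact 95% interval 64.0 to 14165). Tns3, Emp2 and Alox5, the gene of 5-lipoxygenase, also had 1 DMSO count each and ratios of 135 (24.0 to 5377), 88.4 (15.6 to 3520) and 85.6 (15.1 to 3409). Dixdc1, Adamts14 and Scin, the gene of the actin-severing protein scinderin, reached 22.4 ± 6.77, 17.5 ± 5.58 and 34.4 ± 18.3 CPM from means of 0.302, 0.231 and 0.596 CPM.

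The largest falls were in Itgae, Fam71b, Gpld1, Cd6, St6gal1, Bpifb4, Slc28a2b, Zfp683, Ighd and Morc1. Itgae, the alpha chain of the integrin CD103 (chromosome 11, 73090583 to 73147446), fell 8.66-fold, from 181 ± 20.6 to 21.2 ± 6.16 CPM (log2 fold change -3.11, SE 0.15, edgeR adjusted p = 3.40e-09). Cd6, a receptor that tunes T cell receptor signals, fell 7.11-fold, from 186 ± 10.5 to 26.1 ± 2.82 CPM (log2 fold change -2.83, SE 0.08, edgeR adjusted p = 2.11e-11). Fam71b, Gpld1, St6gal1, Bpifb4 and Slc28a2b fell between 6.69-fold and 8.50-fold. Zfp683, the gene of the tissue-residency factor Hobit, fell 5.67-fold, Ighd 5.35-fold and Morc1 5.02-fold. Dot1l itself (chromosome 10, 80755206 to 80795461) was 1.27-fold higher with the inhibitor, at 98.0 ± 6.13 against 77.1 ± 4.44 CPM, and higher in all 4 pairs (log2 fold change 0.35, SE 0.07, edgeR adjusted p = 0.00151). The inhibitor acts on the protein, so this level does not check the labels.

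Of the cytotoxic granule and death ligand genes, 18 of 23 tested members rose (19 adjusted over the list alone) and 0 fell. Besides the granzymes, Gzma rose 4.65-fold and Serpinb9, an inhibitor of granzyme B, rose 3.47-fold. Serpinb9b rose as well, with a log2 fold change of 5.27. Gzmb, the most abundant granzyme, had 1869 ± 151 CPM in DMSO and 2329 ± 611 CPM with SGC-0946 and did not pass (log2 fold change 0.32, SE 0.13, edgeR adjusted p = 0.0611, and 8.85e-04 with the replicate block). The list was called higher by camera (adjusted p = 7.20e-09), with adjusted p = 0.37 with an estimated correlation. Gzmf, Mcpt8 and Gzmc lie with Gzmd, Gzme and Gzmg in a run on chromosome 14, and these 6 genes rose. Mcpt8, a mast cell protease gene, had 1 count in DMSO and 111 with SGC-0946, a ratio of 77.9 (13.7 to 3104), and Gzmf 3 and 223, a ratio of 52.2 (17.6 to 255). Ctsg and Cma1 in the same stretch were below the count filter, with 0 and 95 counts for Ctsg and 1 and 33 for Cma1. Gzmn had 0 and 1.

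**Figure D3:**
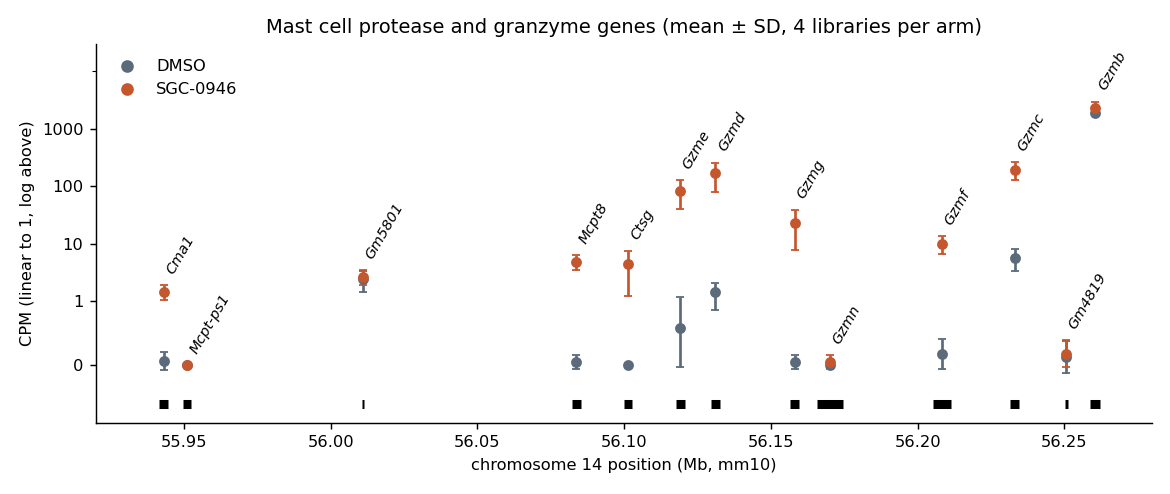
Genes from Cma1 to Gzmb on chromosome 14 (mm10 position in Mb on the x axis, black blocks for genes) with mean ± SD CPM over 4 DMSO and 4 SGC-0946 libraries on the y axis, linear up to 1 and logarithmic above. Gzme, Gzmd, Gzmg, Gzmf, Gzmc and Mcpt8 stand above their DMSO level, while Gzmb has 1869 CPM in DMSO and 2329 CPM with SGC-0946.

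Of the NK cell receptors and their adaptors, 9 of 18 tested members rose (9 adjusted over the list alone) and 3 fell. Fcgr3 and Tyrobp, an Fc receptor and a signalling adaptor, rose with log2 fold changes of 5.66 and 2.44. Klrd1, Klrk1 and Cd7 fell. The list has 31 genes, and the members not tested, Ncr1 and Klrg1 among them, were below the count filter. The list was called higher (camera adjusted p = 0.0173), with adjusted p = 0.40 with an estimated correlation. Of the inhibitory receptors and exhaustion genes, 10 of 16 tested members rose (10 adjusted over the list alone), including Cd244a, Cd160 (3.00-fold), Havcr2 and Lag3. The 3 that fell were Btla (4.12-fold), Ctla4 (2.35-fold) and Vsir. Pdcd1, the gene of PD-1, Tox2 and Cd200 were below the count filter. This list was called higher (camera adjusted p = 0.0339), with adjusted p = 0.44 with an estimated correlation, 0.0522 without DMSO replicate 4 and 0.0821 without SGC replicate 3. Of the effector and effector memory regulators and markers, 11 of 20 rose (11 adjusted over the list alone), including Eomes (1.56-fold), Id2 (1.64-fold) and Zeb2, and 2 fell, Zfp683 and Stat4. It was called higher (camera adjusted p = 0.0448), with adjusted p = 0.44 with an estimated correlation, and 0.0653, 0.0646 and 0.0981 without DMSO replicate 1, DMSO replicate 2 and SGC replicate 3.

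Of the TCR-CD3, CD8 and proximal signalling genes, 18 of 22 fell (18 adjusted over the list alone) and 2 rose, Cd3g and Lcp2. Cd6, Trac and Cd8b1 led the list by p. Cd5, an inhibitory T cell surface receptor, fell with a log2 fold change of -1.92. The list was called lower (camera adjusted p = 4.14e-09), with adjusted p = 0.37 with an estimated correlation. Of the naive and central memory genes, 16 of 21 fell (16 adjusted over the list alone) and 1 rose, Igfbp4. Satb1, a chromatin organiser, fell from 757 ± 14.6 to 283 ± 48.4 CPM, Ccr7, a lymph node homing receptor, from 93.4 ± 5.52 to 35.4 ± 8.33 CPM, and Cd27 from 226 ± 18.3 to 112 ± 23.5 CPM. Tcf7, the gene of the memory factor TCF-1, fell 1.64-fold. This list was called lower (camera adjusted p = 2.31e-06), with adjusted p = 0.40 with an estimated correlation. Of the CD4 and regulatory T cell markers, 5 of 8 fell (5 adjusted over the list alone), including Lrrc32 (4.43-fold), Il2ra (1.98-fold) and Ctla4, and 1 rose, Zbtb7b. It was called lower (camera adjusted p = 0.0173), with adjusted p = 0.40 with an estimated correlation.

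Of the ATF4 and amino acid response genes, 13 of 18 rose (13 adjusted over the list alone), including Asns (2.79-fold), Pck2 (2.23-fold) and Shmt2 (1.55-fold), and 2 fell, Ddit3 and Psph. Of the glycolysis genes, 12 of 20 rose and 1 fell (12 and 2 adjusted over the list alone), including rises of Tpi1 (2.23-fold), Eno1 (1.70-fold) and the lactate exporter Slc16a3 (2.73-fold) and a fall of Eno3. The lists were called higher by camera (adjusted p = 4.10e-05 and 5.34e-04), each with adjusted p = 0.37 with an estimated correlation. Of the cholesterol synthesis and SREBP2 targets, 15 of 26 rose (15 adjusted over the list alone), including Hmgcs1 (1.79-fold) and Hsd17b7 (1.62-fold), and 1 fell, Srebf2. Of the unfolded protein response genes, 10 of 17 rose (10 adjusted over the list alone), including the chaperone genes Pdia6, Calr and Hspa5 (1.71-fold, 1.80-fold and 1.52-fold), and 1 fell, Edem1. Of the nuclear-encoded oxidative phosphorylation genes, 9 of 34 rose (9 adjusted over the list alone), including Atp5b (1.30-fold), Atp5a1 (1.23-fold) and Sdhd (1.18-fold). These 3 lists were called higher by camera (adjusted p = 0.00145, 0.00265 and 0.00423), each with adjusted p = 0.44 with an estimated correlation.

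Of the immediate early and TCR-induced genes, 10 of 22 rose (10 adjusted over the list alone), including Fosb (10.2-fold) and Egr3 (8.34-fold), and 2 fell, Dusp1 (1.77-fold) and Nfkbia. It was called higher (camera adjusted p = 0.0190), with adjusted p = 0.54 with an estimated correlation and 0.0821 without SGC replicate 3. Of the cytosolic ribosomal protein genes, 4 of 47 rose (1 adjusted over the list alone), Rpl38, Rps2, Rpl14 and Rplp1, with a list median of 0.06 on the log2 scale. It was called higher (camera adjusted p = 0.0311), with adjusted p = 0.77 with an estimated correlation. The call was lost when DMSO replicate 2 or 4 or SGC replicate 1, 2 or 3 was left out (camera adjusted p from 0.0617 to 0.124). Of the lysosome genes, 11 of 22 fell (12 adjusted over the list alone), including the cholesterol exporters Npc2 (1.68-fold) and Npc1 (1.61-fold) and the sialidase Neu1 (1.49-fold), and 2 rose, Ctsd and Sqstm1. It was called lower (camera adjusted p = 6.94e-04), with adjusted p = 0.37 with an estimated correlation. Of the listed mitochondrially encoded genes, 6 of 10 tested fell (6 adjusted over the list alone), including mt-Co1 (1.36-fold), mt-Nd4 (1.41-fold) and mt-Nd5 (1.38-fold), and 0 rose. It was called lower (camera adjusted p = 0.00145), with adjusted p = 0.44 with an estimated correlation. The 13 mitochondrially encoded genes of the list made up 3.08 ± 0.235% of the counts in DMSO and 2.36 ± 0.187% with SGC-0946 (SD, n = 4 each). The exact permutation p was 0.0286, and 0.125 with labels exchanged only within pairs, and the share was lower in all 4 pairs. The list and this share leave out the ribosomal RNA genes mt-Rnr1 and mt-Rnr2.

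**Figure D4:**
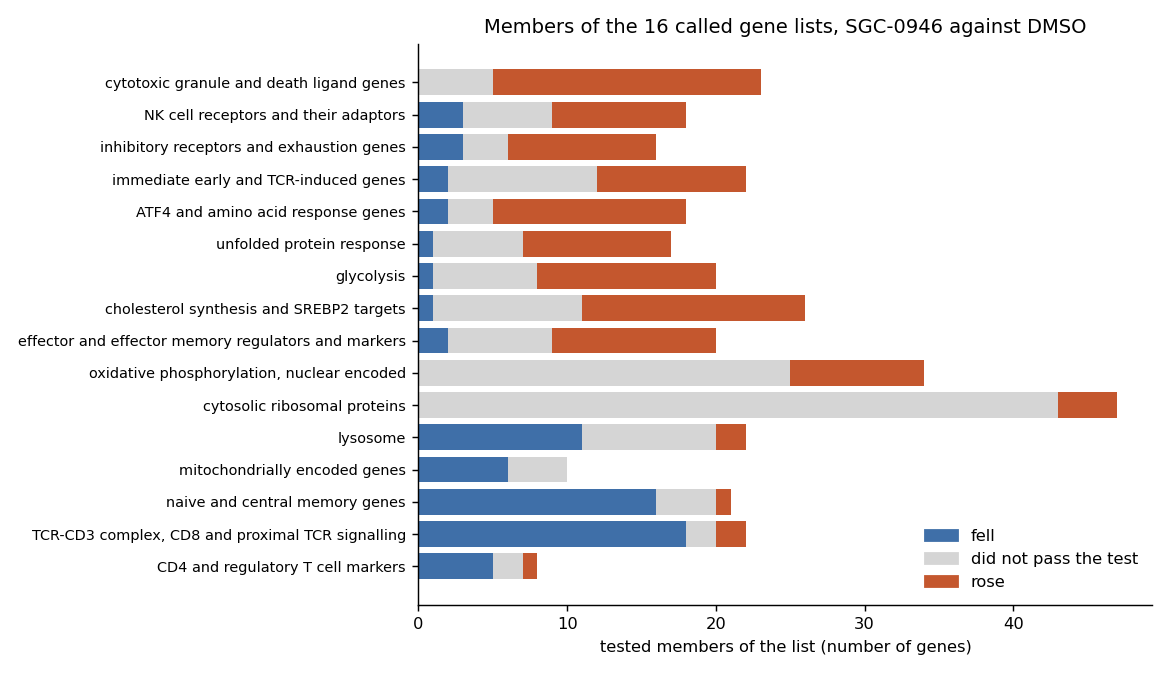
Number of tested members that fell, did not pass the test or rose for the 16 gene lists called by camera, with the number of genes on the x axis and 1 bar per list. The TCR-CD3 and CD8 list has 18 falls in 22 members, and the cytotoxic list 18 rises in 23.

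Further lists held genes moving both ways and were not called by camera. Of the type 1 cytokine and chemokine genes, 4 of 12 rose and 4 fell (4 and 4 adjusted over the list alone). Spp1, Xcl1 and Ifng rose 30.5-fold, 11.8-fold and 4.63-fold, and Lta fell 3.15-fold (camera adjusted p = 0.857). Of the chemokine receptors, integrins and homing genes, 6 of 22 rose and 8 fell (6 and 8 adjusted over the list alone). Itga1, the alpha chain of a collagen-binding integrin, went from 0.658 ± 0.482 to 26.0 ± 9.80 CPM (camera adjusted p = 0.995). Of the costimulatory receptors, 3 of 12 rose and 6 fell (4 and 7 adjusted over the list alone), with Tnfrsf9 rising 3.34-fold and Slamf1 and Cd226 falling 3.14-fold and 2.51-fold (camera adjusted p = 0.162). Of the type 2 and type 17 genes, 3 of 5 rose and 2 fell (3 and 2 adjusted over the list alone). Il1rl1, the IL-33 receptor, rose 18.6-fold, Maf 2.68-fold, and Ccr4 fell 2.71-fold (camera adjusted p = 0.256). Of the IL-2 and STAT5 responsive genes, 5 of 17 rose and 7 fell (6 and 8 adjusted over the list alone), among them Pim3 (2.24-fold up), Il2rb (1.66-fold up) and Socs2 (2.08-fold down), with camera adjusted p = 0.373.

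Of DOT1L, its partners and the elongation complexes, 3 of 14 rose and 3 fell (3 and 4 adjusted over the list alone), with Ell2 rising 2.04-fold and Aff1 falling 1.40-fold (camera adjusted p = 0.822). Of the DOT1L-dependent genes of MLL-rearranged leukaemia, 4 of 5 tested fell, Jmjd1c, Runx2, Cdk6 and Myb, and Pbx3 rose 2.29-fold (4 and 1 adjusted over the list alone). This list had camera adjusted p = 0.0973, 0.0436 with the replicate block and 0.0309 without DMSO replicate 1, with adjusted p = 0.44 with an estimated correlation. Of the PRC2 subunits, 2 of 11 rose and 2 fell (4 and 2 adjusted over the list alone), with Jarid2 rising 1.59-fold and Ezh2 and Ezh1 falling 1.26-fold and 1.19-fold (camera adjusted p = 0.655). Of the other histone lysine methyltransferases and demethylases, 10 of 30 fell and 2 rose (11 and 2 adjusted over the list alone), among them Nsd3 (1.54-fold down), Kdm3a (1.43-fold down) and Kdm6b (1.44-fold up), with camera adjusted p = 0.0920, 0.0175 without DMSO replicate 1, and adjusted p = 0.54 with an estimated correlation.

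Among cell cycle and survival genes, 5 of 25 G1 and S phase genes rose and 1 fell (3 and 1 adjusted over the list alone). Gins2 and Mcm2 rose 1.52-fold and 1.31-fold and E2f2 fell 1.59-fold, with camera adjusted p = 0.0874, 0.0119 with the replicate block, and adjusted p = 0.80 with an estimated correlation. Without DMSO replicate 1, SGC replicate 2 or SGC replicate 3 it was 0.0141, 0.0228 and 0.00663. Of the G2 and M phase genes, 2 of 25 fell, Cenpa (1.34-fold) and Nusap1 (1.16-fold), and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.440). Plk1 had a log2 fold change of 0.22 (edgeR adjusted p = 0.0852, and 0.0167 with the replicate block). Of the CDK inhibitors and p53 targets, 9 of 20 fell and 3 rose (9 and 3 adjusted over the list alone), with Zmat3 and Trp53inp1 falling 1.81-fold and 1.60-fold and Perp rising 4.01-fold (camera adjusted p = 0.170). Of the BCL-2 family, 6 of 13 fell and 2 rose (6 and 3 adjusted over the list alone), with the death-promoting Bcl2l11 and Pmaip1 falling 1.66-fold and 1.68-fold and Bcl2 itself 1.31-fold (camera adjusted p = 0.162).

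Of the interferon-stimulated genes, 11 of 30 fell and 4 rose (11 and 5 adjusted over the list alone), with Ifit3 and Trim30a falling 1.90-fold and 1.41-fold and Oasl2 rising 2.08-fold (camera adjusted p = 0.427). Of the MHC class I presentation genes, 3 of 19 rose and 2 fell (3 and 2 adjusted over the list alone), with Psmb10 and H2-Q6 rising 1.26-fold and 1.17-fold and H2-T23 falling 1.23-fold (camera adjusted p = 0.256). Of the fatty acid synthesis and LXR targets, 5 of 18 rose and 2 fell (5 and 2 adjusted over the list alone), with Scd1 and Fads2 rising 3.51-fold and 1.80-fold, Me1 rising with a log2 fold change of 3.85, and Elovl5 falling 1.46-fold (camera adjusted p = 0.456). The sign of the list median, mean or test differed in 5 lists. The mean was above 0 and the median and test below for the DOT1L partners (0.01 and -0.03), type 1 cytokines (0.63 and -0.02) and interferon-stimulated genes (0.03 and -0.001). In the PRC2 subunits the median was -0.03, with the mean at 0.05 and the test upward. In the homing genes the median and mean were 0.05 and 0.04, with the test downward.

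Markers of other cell types were mostly below the count filter. Of the B cell markers, 3 of 4 tested fell, Ighm (4.05-fold), Ighd and Cd79b (2.39-fold), and 1 rose, Bank1 (3 and 1 adjusted over the list alone). The list had camera adjusted p = 0.0874, 0.0460 with the replicate block and 0.0421 without SGC replicate 4, with adjusted p = 0.40 with an estimated correlation. Ighm, the constant region of IgM heavy chain (chromosome 12, 113418558 to 113422730), had 720.3 ± 67.2 CPM in DMSO and 178 ± 69.7 CPM with SGC-0946. Of the dendritic cell and MHC class II genes, 2 of 3 tested rose, H2-Ab1 (9.37-fold, to a mean of 5.61 CPM) and Itgax (2.64-fold), and H2-DMa did not pass (2 up and 1 down adjusted over the list alone, camera adjusted p = 0.162). Of the gamma-delta and innate-like T cell markers, 4 of 8 fell, led by Trgc1 (2.92-fold), Trdc (1.32-fold) and Trgc4 (3.45-fold), and 0 rose (4 down and 2 up adjusted over the list alone, camera adjusted p = 0.162). The other 3 lists had fewer than 3 tested members. Cd68 and Ms4a6c of the myeloid markers did not pass (edgeR adjusted p = 0.0673 and 0.464, and 0.0436 for Cd68 with the replicate block), nor did the megakaryocyte marker Itga2b (edgeR adjusted p = 0.357). Of the stromal and endothelial markers, both tested members fell, Pecam1 1.61-fold and Kdr 3.00-fold (0 up and 2 down adjusted over the list alone).

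None of the 16 list calls held with an estimated correlation, and another split of the same 8 libraries into 4 and 4 also called 16 lists by camera. The genes higher by at least 2-fold with SGC-0946 numbered 1011 with no count filter and 309 with a filter of 5 CPM in 4 samples.

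The second comparison asked whether the effect differed between male and female pairs, a question the labels do not state. The gene with the smallest p was Lars2, a mitochondrial leucyl-tRNA synthetase, whose log2 fold change with SGC-0946 was 0.30 in male and -0.60 in female pairs (difference 0.90, SE 0.16). The edgeR interaction test called 0 of 10900 genes, with 254 at an unadjusted p under 0.05 and an adjusted p = 0.831 for Lars2. With the replicate block the test called 2 genes, among them Lars2 (difference 0.90, SE 0.12, edgeR adjusted p = 4.87e-04). Mir6236, with the next smallest p without the block, had log2 fold changes of 0.42 in male and -1.05 in female pairs. It was called only with no count filter (edgeR adjusted p = 0.120 with the replicate block). Whether the reads counted at Lars2 came from its own transcript was not tested. DESeq2 called 1, Lars2, and edgeR called 8 genes with no count filter and 22 without replicate 3, where a single female pair remained and was assumed to vary like the male pairs.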

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

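The tests of B cell transcripts, the counts of genes ranked by level and the test of basophil transcripts other than Kit were chosen only after the results were seen.

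Of 256 groups of 4 libraries checked with Dixon's criterion, on log2 CPM for genes and on the value itself for library totals and shares, 17 held a library apart from the other 3, where chance gives about 1 in 20, or 12.8. Single reads made 4 of them: Gzmg at 0.214 CPM in DMSO replicate 4, Tns3 and Emp2 at 0.249 CPM each in DMSO replicate 3, and Alox5 at 0.286 CPM in DMSO replicate 2, with 0 in the other DMSO libraries. Gzme stood at 1.5 CPM in DMSO replicate 4, above the other DMSO libraries. SGC replicate 4 stood apart in Cd27 (77.2 CPM, lowest), Tnfrsf9 (493 CPM, highest), Scd1 (35.2 CPM, lowest), Trgc1 (12.1 CPM, highest) and the share of counts in the 10 most abundant genes (5.65%, lowest). SGC replicate 1 was lowest of its arm in Runx2 (85.1 CPM), Maf (18.8 CPM) and Oasl2 (13.8 CPM). DMSO replicate 2 was lowest in Serpinb9 (103 CPM) and highest in mt-Co1 (14300 CPM) and mt-Nd5 (4990 CPM). Ccr7 was highest in DMSO replicate 4 (102 CPM).

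The effect of the inhibitor on the reads counted at Lars2 differed between male and female pairs when replicates were paired. The difference, male minus female, was 0.90 on the log2 scale (edgeR adjusted p = 4.87e-04).

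More genes rose than fell by at least 2-fold, 507 against 191. The higher totals of mouse counts in the inhibitor libraries are argued against as the whole cause. The ratio was 2.31 (SD 0.0737 over 10 draws) after thinning all libraries to 3514221 counts, against 2.65 before. Genes near the detection floor cannot be told apart as a cause. Among the 7871 genes with an average log2 CPM of at least 4, the ratio was 1.58 (128 against 81), with an exact 95% interval of 1.19 to 2.11 that reaches below the bound set for excluding it, and in the highest 8720 genes the counts depended on the arm that set the level, with 85 rises against 131 falls by DMSO, 225 against 73 by SGC-0946 and 140 against 105 by the mean of both. An effect of the treatment stays open, as does a change in total RNA per cell, which was not measured.

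Ighm and Ighd fell, although the cells are labelled CD8 T cells. For Ighm, fewer B cells with the inhibitor are argued against by the DMSO libraries, where Cd79a and Igkc together reached at most 0.117% of its CPM (Cd79a is also in the B cell list). For Ighd, Cd79a and Igkc reached up to 12% of its CPM in a DMSO library, from few counts, which decides nothing. Over the DMSO libraries Igkc and Cd74, which B cells hold in larger amounts than Ighd, together had 19 counts against 110 of Ighd, or 17.3% (exact 95% interval 10.0% to 28.3%), which goes against fewer B cells for Ighd. Cd79b, also in the B cell list, goes the other way. It had 167 counts in DMSO and fell along with Ighd, from 10.6 to 4.44 CPM. Fewer B cells therefore stay open for Ighd. Reads of overlapping transcripts stay open, because the strand setting is not known, and so does an effect of the treatment, as a hypothesis.

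A run of granzyme and mast cell protease genes on chromosome 14 rose. Reads shared among copies are argued against as the whole cause, since the median of 80.2% of 50-base words of Gzmc, Gzmd, Gzme, Gzmf and Gzmg occur in no other gene and the ratio of Gzmd to Gzmc was 0.229 to 0.286 in DMSO and 0.687 to 1.06 with SGC-0946. The DMSO ratios rest on 24 counts of Gzmd and 93 of Gzmc. Sharing among Gzmd, Gzme and Gzmg, with 78.1%, 79.4% and 80.2% of words in no other gene, was not tested by this ratio. Basophils or mast cells met the criterion written for them, as Cpa3, Ms4a2, Kit and Hdc together reached up to 6420% of the CPM of Mcpt8, but Kit, which rose from 29.5 to 170 CPM, made most of it, and without Kit they reached 34.5% to 100%. Ms4a2, Cd200r3 and Prss34 together had 1 count against 111 of Mcpt8, or 0.901% (exact 95% interval 0.0226% to 5.12%), and Ms4a2, a gene of both cell types, had 0, which argues against basophils, and less firmly against mast cells, as Kit rose with the pattern and Cpa3, below the count filter, had 0.659 CPM in DMSO and 2.59 CPM with SGC-0946. NK cells cannot be told apart as a source, since Ncr1, Klra4, Klra8 and Klra9 together reached 3.8% of the CPM of Klrb1c, between the bounds set, mostly from Ncr1 (0 CPM in DMSO and 1.97 with SGC-0946), while Klra4, Klra8 and Klra9 had 1 count each with SGC-0946 against 1393 of Klrb1c, Klre1 had 2.98 CPM in both arms and Klrd1 fell from 335 to 271 CPM, so the pattern is not assigned to the treated T cells alone.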

How the results depend on the processing

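Thinning to equal totals, the filter of 5 CPM in 4 samples and the exchange of labels within pairs for library shares were chosen only after the results were seen.

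The count of genes changed between SGC-0946 and DMSO ranged from 3018 to 4736 over the alternatives, each within 1.5 times the reported 4041, and 73.1% to 99.6% of the reported calls were made again in the same direction. The genes higher by at least 2-fold with SGC-0946 numbered 1011 with no count filter, which tests 20588 genes, and 309 with 5 CPM in 4 samples, which tests 9837. The planned filter of 1 CPM in 4 samples tested 11838 genes, more than the 10900 of the main filter. The replicate block gave 4736 calls. It changed the calls of Plk1, Cd68, Gzmb, Lars2 by sex and 3 gene lists, and no other call among the lists and the genes named by the rule.

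For the treatment effect compared between female and male pairs, edgeR called 8 genes with no low-count filter and 2 with the replicate block, DESeq2 called 1, and the sets without 1 replicate called 0 to 22. The 22 came without replicate 3, and 2 without replicate 4. The cause was not tested. Lars2 had a log2 fold change over all pairs of -0.14, which did not pass. It ranged from -0.37 without replicate 1 (edgeR adjusted p = 0.0465) to 0.049 without replicate 3, where its sign reversed.

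Of the gene list tests, 16 were called. With the correlation estimated per list, 0 were called, 0 gene lists higher with SGC-0946 and 0 gene lists lower with SGC-0946 (camera, 0 with an estimated correlation, and 24 with fry). Fry, which asks whether the genes move 1 way rather than how they compare with other genes, called 12 gene lists lower with SGC-0946, and it did not call the ribosomal proteins (adjusted p = 0.197) or the immediate early genes (adjusted p = 0.0851). The inhibitory receptors were not called with 1 CPM or 5 CPM in 4 samples (camera adjusted p = 0.0778 and 0.0828), nor the effector genes with 5 CPM (0.0688).

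Of 125 genes named by the rule, 119 were called, and their alternatives gave the reported direction and call in 2693 cases, lost the call in 33, gained it in 9 and reversed in 1. Nusap1, Ezh1, Ezh2, Mcm2, Rpl14, Rps2 and H2-Q6 lost their calls in some sets without 1 library or pair. Nusap1 also lost it with DESeq2, limma-voom and library size only (adjusted p = 0.0605, 0.0560 and 0.0562), and Ezh1 after thinning (edgeR adjusted p = 0.150). The difference in the share of counts from mitochondrially encoded genes ranged from -0.785 to -0.612 percentage points in sets without 1 library. With the replicate block, that is with labels exchanged only within pairs, it was -0.725 with an exact permutation p = 0.125, the smallest that 4 pairs allow. Scaling to yeast RNA was not run. Of all genes, 23 had 0 counts in DMSO and at least 20 with SGC-0946, and 0 had the reverse. These are raw counts, and the higher mouse count totals with SGC-0946 (mean 5.60 M against 3.96 M) make the first case easier to reach.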

Other observations

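The test of baseline expression and the draws of neighbouring genes matched on expression were chosen only after the results were seen.

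Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, called as many as 4041 genes, and the highest of the others called 6. That highest split was the split by sex. Among the 8 splits that part all 4 pairs, the highest other called 0. Each of the other splits mixes treated and vehicle libraries, so the treatment difference itself keeps their calls low. The smallest share that this comparison can give is 1 in 35, so it does not by itself exclude chance for the gene calls. For the gene lists, 2 of the 35 splits called at least 16 lists, the real one included, so chance cannot be excluded for their number. The split by sex called 13 lists, and the highest other split that parts all 4 pairs called 12.

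Genes that rose by at least 2-fold lay next to each other, in the genomic order of the tested genes, more often than random tested genes, and untested genes can lie between them. Of 507 genes, 37 neighbouring pairs did not share the first 3 letters of their symbols. Random draws, 10000 in number, gave a mean of 22.7 (14 to 32, one-sided permutation p = 0.0027). Draws matched on expression gave a mean of 22.3 (one-sided permutation p = 0.0018). Related genes with unlike symbols, such as Mcpt8 and Gzme, stay among these pairs. With pairs of like symbols included there were 52 pairs against 23.5 (permutation p = 1e-04, the smallest that the draws can give). A candidate explanation is a shared local effect on neighbouring genes, which was not tested further.

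Protein-coding genes that fell had a median length of 32.1 kb, those that rose 24.5 kb and those not called 22.4 kb. The ratio of fell to rose was 1.31, with a bootstrap 95% interval of 1.21 to 1.46 that lies above 1, so the genes that fell were longer. It stayed within the bounds of 0.67 to 1.5 set for it. This argues against a ratio over 1.5, not against a smaller link of gene length to the direction.

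Genes that are low in vehicle may have gained most. With the baseline from DMSO replicates 1 and 2 and the change from replicates 3 and 4, the median log2 change was 0.15 in the 2180 genes with the lowest baseline and -0.02 in the 2180 with the highest. By this change, taken without a test, 396 genes were at least 2-fold higher and 72 at least 2-fold lower in the lowest group, and 6 and 45 in the highest. The count filter used the libraries of both arms, so a gene too low in DMSO was kept only through its level with SGC-0946. Such genes favour rises in the lowest group, so its median and counts cannot tell a gain from this selection. The difference of 0.17 lay between the bounds of 0.1 and 0.2 and leaves this open.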
